A study of Mus musculus with 24 samples.

How the data were processed

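The series holds 24 mouse samples in 16 groups: 11 of Rev-erbα, 8 of the corepressor subunit HDAC3, 3 of related receptors of the ROR family, and 2 inputs. They come from liver (19), eWAT (3) and the ventral tegmental area of the brain (2). The files used here cover 3 groups, Rev-erbα ChIP-seq of eWAT (2 libraries) and of brain (1 library) and Rev-erbα ChIP-exo of liver (2 libraries), all from wild-type C57BL/6 mice at zeitgeber time 10, per the labels. The other 13 groups (19 samples), among them the inputs, the liver ChIP-seq of both strains, the mutant of the DNA-binding domain and the HDAC3 and ROR libraries, were not analysed here. The labels give replicate numbers for eWAT and the ChIP-exo, and the series design calls replicates biological; since the files hold 1 list per group, no spread between replicates could be computed.

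Per the labels' protocols, tissue was crosslinked with formaldehyde and sonicated before immunoprecipitation, and in ChIP-exo the DNA was digested on the beads with lambda and RecJf exonucleases before elution. The submitters' processing notes name the mm9 build, Bowtie 0.12.8 for the ChIP-seq samples, Bowtie 1.1.1 for the ChIP-exo samples and HOMER with no version for both, without roles. Settings of the peak and border callers, thresholds, use of the inputs and pooling of replicates are not given in the sources used here. Each peak line carries the authors' score, whose unit the files do not define. In eWAT the deposited scores run from 10.1 to 281.6 (median 14.2) and all lie within 0.05 of a whole multiple of 1.013; in brain they run from 14.5 to 516.3 (median 25.5) in multiples of 3.636, a step 3.59-fold as wide. Such steps arise when whole read counts are rescaled by 1 factor per list; in these steps the eWAT peaks run from 10 to 278 (median 14) and the brain peaks from 4 to 142 (median 7). Read totals are not given, so apart from the width and number of these steps scores were compared only within a list, to rank or filter peaks. Per the file headers, each ChIP-exo border has a signal (0.0602 to 343.3, median 0.471, scale not stated) and a p-value (0.005 to 0.05, so the deposited list was evidently limited at that level). Another threshold or depth would give the authors' lists fewer or more sites, and percentages of shared sites would move with them.

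Coordinates fit the mm9 chromosome lengths for all 9016 and 10687 peaks and 245360 borders. Analysis used the mm9 (NCBIM37) sequence and its GENCODE vM1 gene models, with 22350 protein-coding genes and 70018 transcription starts on chromosomes 1 to 19 and X; 245086 borders lie there. A peak was placed by its central base, first as within 1 kb of a start, then exon, intron or intergenic. A location given in the text is that of the centre in any protein-coding gene, and its distance is to the nearest start of the gene named. All 217 list symbols were matched, 3 of them by an older symbol taken from RefSeq names (GRCm38, names only).

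Except for the motifs in border pairs, the following tests were fixed before the data were examined. Shared peaks overlap by at least 1 bp; the chance level came from 1000 random placements of the other list within its chromosomes. A liver border was counted within 100 bp of a peak centre. Border pairs join a plus border to the next minus border downstream within 200 bp; the share with a partner 5 to 60 bp away was compared with 100 offsets of the minus borders by 1 to 10 kb. Motifs were 17 fixed consensus sequences, searched on both strands within 50 bp of each centre and in the same width 1000 bp to each side. The search of border pairs added 10 bp on each side. Gene lists (12) were tested by Fisher's exact test, two-sided, for genes with a site within 10 kb of a start, adjusted by the Benjamini-Hochberg method over lists and the 3 sets (eWAT, brain, liver border pairs), and between tissues by an exact McNemar test adjusted over lists. Other families were adjusted over their 15 motifs or 3 comparisons, and the motifs in border pairs over all motifs and spacings searched. The threshold was 0.05. Intervals of percentages are 95% Wilson intervals and those of odds ratios are exact conditional ones; both cover counting error only. Neighbouring sites and genes are not independent, so p-values over them are too small by an unknown amount.

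Named genes were chosen by a rule written before the data were examined: every core clock gene with a peak within 10 kb, up to 6 members of each other list by peak score, the 10 highest-scoring peaks of each list, and the 10 shared peaks with the best mean rank. Peaks with over 10 peaks of their list within 100 kb were counted but not named; these were 34 brain peaks and 0 eWAT peaks, and the 4 brain peaks shown near Nr1d1 are the exceptions, named after their values were seen. Results for 6 genes that the rule selects are not reported.

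The tests were checked on simulated data. With lists placed at random (9016 peaks), overlap was called in 2% and border proximity in 8% of 100 simulations; with 50 planted sites both were called in 100%, with a mean excess of 50.9 and 52.0. The planted spacing of 1000 pairs among 122296 plus borders was recovered in 100% of 20 simulations, and 0% were called without one. Of 1000 random lists of 20 genes among 22350, 1.6% were called, and 100% of those with 10 genes near an eWAT peak. Planted motifs were found in 100% of 1700 sequences. These were runs of A or of T, in which no motif can occur by itself, so false matches were not tested. A shift of the eWAT score median by 2 was called in 99% of 100 simulations and no shift in 0%.

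Alternatives fixed in advance were stricter score limits, other overlap rules and distances, local random placement, other motif, promoter and gene windows, nearest-gene assignment and lists of equal length. Added after seeing the data were the opposite orientation as a background, the restriction to peaks over 1 kb from every start, the test of tissue-specific genes against all other genes, the motifs at border pairs and the promoter share with brain peaks matched in number, as well as the E-boxes by sharing and the tests of HNF6 sites, read depth and chance peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.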

Results

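Binding of the nuclear receptor Rev-erbα (gene Nr1d1), a heme-binding transcriptional repressor of the circadian clock, was mapped in mouse tissues collected 10 h after lights on (zeitgeber time 10). The series held 24 samples in 16 groups, of which 3 groups were analysed here. Rev-erbα ChIP-seq of epididymal white adipose tissue (eWAT, 2 libraries) and of the ventral tegmental area of the brain (brain, 1 library) was represented by 1 peak list per tissue. Rev-erbα ChIP-exo of liver (2 libraries), in which exonucleases trim the precipitated DNA up to the crosslinked protein, was represented by 1 list of strand-specific borders. The eWAT list held 9016 peaks and the brain list 10687 peaks, each 150 bp wide, and the liver list held 245360 borders, 122429 on the plus strand and 122931 on the minus strand. The sequencing depth was unknown, and no value per replicate was at hand, so each p-value below describes sites or genes in these lists and not variation between animals. Apart from their steps, scores were compared within a list only, and all coordinates are 1-based on mm9.

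The strongest Rev-erbα sites of both tissues lay at genes of the circadian clock. Of the 10 highest-scoring eWAT peaks, 8 had a core clock gene as their nearest gene, as did 8 of the 10 highest-scoring brain peaks and 8 of the 10 best-ranked shared peaks that the naming rule allows, which leaves the strong sites at Nr1d1 out of these last 2 sets. In eWAT, the first 2 ranks and rank 4 fell to Nr1d1 itself. Rank 3 fell to Dbp, a PAR bZIP activator of clock output genes, and ranks 5 and 6 to Per1 and Per2, repressors of the core clock loop. Rank 9 was at Ciart, annotated as Gm129 in the gene models used. In brain, Nr1d2 (the paralog Rev-erbβ) held rank 3 with a score of 421.8 and Bhlhe41, a repressor that binds E-boxes, rank 4 with 396.3. Dbp held rank 5 with 396.3, Per2 rank 6 with 381.8, Tef, a PAR bZIP activator, rank 8 with 345.4, and Ciart and Per1 ranks 9 and 10, both with 338.2. The 2 of these shared sites outside the clock list were nearest to Katnal1 (chromosome 5, 149806812 to 149806961, intergenic, 88 bp upstream of its start) and Igsf8 (chromosome 1, 174240286 to 174240435, in an intron). The eWAT peak of rank 8 was intergenic on chromosome 6 (91549088 to 91549237), 83134 bp from the nearest annotated start, that of Lsm3, and that of rank 10 lay in an intron of Rere (chromosome 4, 149957670 to 149957819).

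Of the 23 core clock genes fixed in advance, 19 had an eWAT peak within 10 kb of a transcription start, against 14.1% of the other protein-coding genes (odds ratio 28.8, 95% interval 9.57 to 116.6, Fisher's exact test, adjusted p = 1.36e-11). A brain peak was listed for 21, against 27.8% (odds ratio 27.2, 6.65 to 239.5, Fisher's exact test, adjusted p = 3.65e-09). For 14 of the 19 genes the best eWAT peak overlapped a brain peak. The best peaks of the clock genes had a median rank of 35 of 9016 in eWAT and of 25 of 10687 in brain, and 10 and 14 of them, respectively, were within the first 100. The shared Dbp site lay in exonic sequence (chromosome 7, 52963058 to 52963207, eWAT score 237.1, rank 3; brain rank 5). The shared Per2 site lay 70 bp upstream of a start (chromosome 1, 93355902 to 93356051, eWAT score 210.7; rank 6 in both lists), and the shared Per1 site 347 bp upstream (chromosome 11, 68908297 to 68908446, eWAT score 215.8, rank 5; brain rank 10). Bhlhe41 carried an intergenic shared site 9457 bp downstream of its start (chromosome 6, 145804290 to 145804439, eWAT score 187.4, rank 12). Cry2 carried an intronic one (chromosome 2, 92263982 to 92264131, eWAT score 181.3, rank 13) and Nr1d2 an intronic one (chromosome 14, 19071041 to 19071190, eWAT score 121.6, rank 31). Npas2, a partner of the activator BMAL1, had a shared site with a Rev-erbα response element 895 bp upstream of its start (chromosome 1, 39249606 to 39249755, eWAT score 116.5, rank 35; brain rank 52). The shared intronic site of Rora also held such an element (chromosome 9, 69187137 to 69187286, eWAT score 55.7, rank 226).

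Not every clock gene ranked high. Arntl, which encodes BMAL1, had a brain peak at its start (chromosome 7, 120350918 to 120351067, exon, score 167.3, rank 37) and no listed eWAT peak within 10 kb. Clock, its partner, ranked 4594 in eWAT and 1003 in brain, and Cry1 ranked 4251 in eWAT and 137 in brain, from different sites. The best eWAT peaks of Tef, Bhlhe40, Nfil3, Hlf and Per3 ranked 23, 196, 566, 816 and 1231. In brain, Cry2, Bhlhe40, Per3, Hlf, Nfil3, Rora and Csnk1e ranked 14, 20, 25, 57, 424, 2708 and 4987. Rorb and Csnk1d had no listed peak within 10 kb in either tissue.

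At Nr1d1 on chromosome 11, the same 3 sites were bound in both tissues. The eWAT peaks lay at 98644730 to 98644879 (intergenic, 8158 bp upstream of the start, score 281.6, rank 1), at 98636609 to 98636758 (37 bp upstream of the start, score 260.4, rank 2) and at 98635098 to 98635247 (in an intron, 1380 bp downstream of the start, score 234, rank 4). The brain peaks at these sites ranked 2, 1 and 7 with scores of 494.5, 516.3 and 370.9. They lie in a 100 kb stretch with 11 brain peaks, which the naming rule leaves out, and are named here after their values were seen. A further brain peak with a score of 29.1 (rank 4794), named under the same exception, had no eWAT counterpart. It lies beyond the end of Nr1d1, inside the overlapping gene Thra. Each of the 3 eWAT peaks had 2 or 3 liver borders within 100 bp of its centre.

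**Figure D1:**
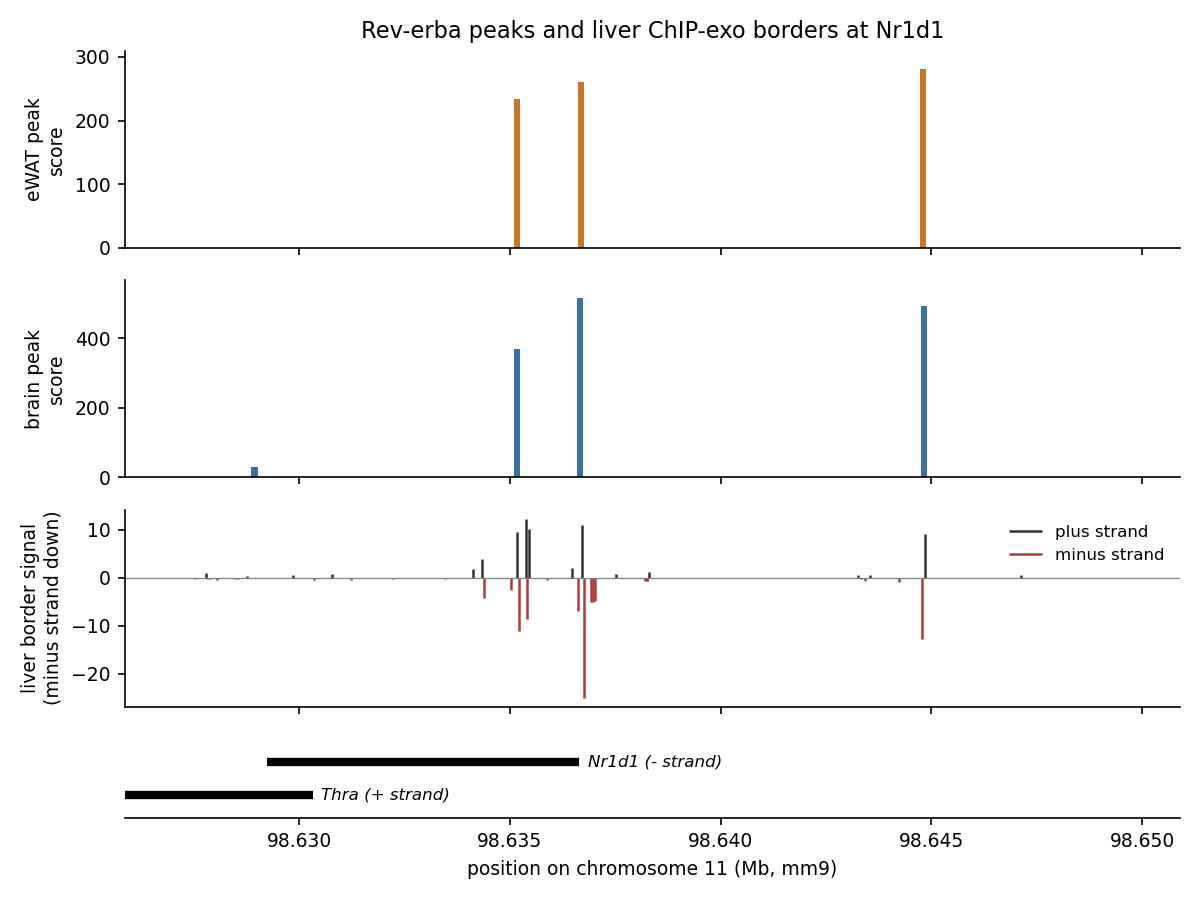
Rev-erbα sites at Nr1d1 in mm9 coordinates (horizontal axis, Mb on chromosome 11): bars give the authors' score of each 150 bp eWAT peak (upper panel) and brain peak (second panel), vertical lines the signal of each liver ChIP-exo border with the minus strand drawn downward, and black bars the genes. The 3 eWAT peaks, with scores of 281.6, 260.4 and 234, each have a brain peak and liver borders at the same place.

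Away from these loci most sites were found in 1 tissue only. Of the eWAT peaks, 706 of 9016 overlapped a brain peak by at least 1 bp (7.83%, 95% Wilson interval 7.29 to 8.40). Of the brain peaks, 706 of 10687 overlapped an eWAT peak (6.61%, 6.15 to 7.09). Random placement of the other list within its chromosomes gave 11.6 ± 3.40 (SD, 1000 placements) and 11.8 ± 3.42 overlaps. The observed overlap was 61-fold and 59.7-fold the chance level (permutation test, one-sided, p = 0.001 each, the smallest that 1000 placements can give). When peaks were moved by only 10 to 100 kb, chance gave 24.3 overlaps in each direction, and the observed overlap was 29.01-fold and 29.03-fold. Among peaks scoring above the median of their lists, 435 of 4437 eWAT peaks (9.80%) and 435 of 5168 brain peaks (8.42%) were shared. Shared sites scored higher, with a median of 27.4 against 14.2 for eWAT-only peaks and of 36.4 against 25.5 for brain-only peaks (permutation test, two-sided, p = 1e-05 each, the smallest that 100000 resamples can give). In the top score decile 32.9% of eWAT peaks (29.9 to 36.1) and 21.7% of brain peaks (19.3 to 24.3) were shared, and in the lowest decile 2.44% (1.62 to 3.67) and 3.09% (2.21 to 4.31).

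The liver list served to ask whether sites seen in both tissues were also occupied in a further tissue. A liver border lay within 100 bp of the centre of 2703 of 9016 eWAT peaks (30.0%, 29.04 to 30.9) and of 3893 of 10687 brain peaks (36.4%, 35.5 to 37.3), against 1.41% ± 0.125 and 1.43% ± 0.113 for randomly placed peaks (permutation test, one-sided, p = 0.001 each, again the smallest possible). When peaks were moved by only 10 to 100 kb, the chance level was 2.58% and 2.78%. Neither kind of placement keeps the distance of peaks to transcription starts, so these chance levels do not allow for promoter position. With borders counted only where a minus border lay 5 to 60 bp downstream of a plus border, 11.6% of eWAT and 10.9% of brain peaks had one. Shared sites had a liver border more often than eWAT-only sites (423 of 706, 59.9%, against 2280 of 8310, 27.4%; odds ratio 3.95, 3.37 to 4.65, Fisher's exact test, two-sided, p = 2.44e-66). The same held against brain-only sites (418 of 706, 59.2%, against 3475 of 9981, 34.8%; odds ratio 2.72, 2.32 to 3.19, Fisher's exact test, p = 6.26e-37). Within score quartiles the eWAT odds ratios were 3.20, 2.37, 1.36 and 2.59 from highest to lowest, the third of them not passing Fisher's exact test (p = 0.233). The brain odds ratios were 1.56, 1.72, 3.03 and 2.50, all passing. Over 1 kb from every transcription start the eWAT odds ratio was 3.21 (53.1% of shared against 26.1% of eWAT-only peaks). The brain odds ratio there was 4.69 (52.1% of shared against 18.8% of brain-only peaks). Away from starts, brain-only peaks thus had a liver border less often than eWAT-only peaks, the reverse of the order over all peaks.

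**Figure D2:**
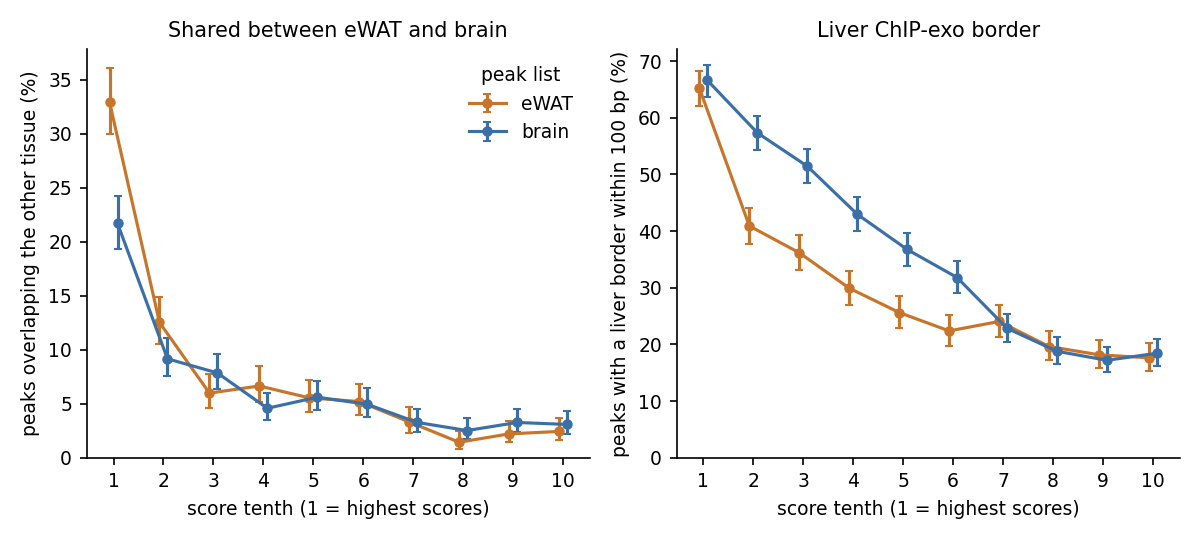
Percentage of peaks that overlap the other tissue's list (left) and that have a liver ChIP-exo border within 100 bp of the centre (right), by score decile of each list with the highest scores at 1; points are eWAT (orange) and brain (blue) and bars are 95% Wilson intervals. Sharing falls from 32.9% to 2.44% in eWAT and from 21.7% to 3.09% in brain, and the border percentage from 65.2% to 17.6% and from 66.6% to 18.4%.

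Genes of fat metabolism carried Rev-erbα peaks in eWAT. Of 27 adipocyte genes, 19 had an eWAT peak within 10 kb (70.4%, 51.5 to 84.2), against 14.1% of other genes (odds ratio 14.4, 6.02 to 38.1, Fisher's exact test, adjusted p = 9.56e-10). The best-ranked were Dgat2, which makes triglycerides (chromosome 7, 106331484 to 106331633, 336 bp upstream of its start, score 103.3, rank 43, shared with brain), Klb, a coreceptor for FGF21 (chromosome 5, 65742127 to 65742276, intron, rank 235), and Pnpla2, the adipose triglyceride lipase (chromosome 7, 148642794 to 148642943, in an intron 48 bp upstream of a further start, with a Rev-erbα response element, rank 330). Next came Agpat2 (rank 544), Fabp4, a fatty acid carrier (rank 980), and Pparg, the master regulator of adipocyte differentiation (chromosome 6, 115371749 to 115371898, intron, rank 999). In brain 10 of these 27 genes had a peak (37.04%, 21.5 to 55.8, against 27.9%), which did not pass (odds ratio 1.52, Fisher's exact test, adjusted p = 0.471). The best-ranked were at Dgat2 (271), Cebpb (792), Thrsp (1588), Pnpla2 (1594), Cebpa (2622) and Acsl1 (2659). Counting genes with a peak in 1 tissue only, 11 adipocyte genes had it in eWAT and 2 in brain. This difference did not pass after correction over the 12 lists (exact McNemar test, p = 0.0225, adjusted p = 0.135). It passed when each peak was assigned to its nearest gene (13 and 1 genes, adjusted p = 0.022, exact McNemar test), but not within 1 kb or 50 kb of a start (7 and 2 genes each, adjusted p = 0.431 and 0.539). It also passed when the 11 and 2 genes were compared with all other genes, of which 1697 had a peak in eWAT only and 4766 in brain only (odds ratio 15.4, Fisher's exact test, adjusted p = 2.27e-04), though not within 50 kb (odds ratio 7.175, adjusted p = 0.0902).

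Neuronal genes had more peaks in brain than in eWAT, as did genes overall. Of 24 neuron genes 9 had a brain peak (37.5%, 21.2 to 57.3) and 2 an eWAT peak (8.33%, 2.32 to 25.9). Neither count passed Fisher's exact test against other genes (odds ratio 1.55, adjusted p = 0.520, and 0.548, adjusted p = 0.702). With nearest genes the brain count passed (13 of 24, odds ratio 2.82, exact test, adjusted p = 0.0358). A peak in 1 tissue only was listed for 7 genes in brain and 0 in eWAT (exact McNemar test, p = 0.0156, adjusted p = 0.135). The adjusted p of this exact test was 0.0234 with nearest genes, 0.0469 within 50 kb and 0.431 within 1 kb. Against all other genes, of which 4761 had a peak in brain only and 1708 in eWAT only, the difference did not pass within 10 kb (Fisher's exact test, adjusted p = 0.482), within 50 kb (adjusted p = 0.212) or with nearest genes (adjusted p = 0.0567). Map2, a dendrite protein, had the highest-ranked of the brain-only peaks (chromosome 1, 66418079 to 66418228, in an intron, with a Rev-erbα response element, rank 212), while the peaks of Elavl3 and Camk2a, each upstream of the start, were shared with eWAT. Snap25, Ncam1 and Nefm ranked 3142, 3549 and 3808 in brain. Of 18 dopamine neuron genes 2 had a brain peak, En2 (rank 997) and Nr4a2 (rank 4126), and 1 gene an eWAT peak, which did not pass (Fisher's exact test, adjusted p = 0.351 and 0.687). Within 50 kb the dopamine neuron genes had fewer peaks than other genes in brain (3 of 18 against 51.1%, odds ratio 0.191, exact test, adjusted p = 0.0135) and in eWAT (1 of 18 against 38.8%, odds ratio 0.0927, adjusted p = 0.0108). In the exact McNemar tests between tissues at 10 kb none of the 12 lists passed after adjustment, and 2 had an unadjusted p under 0.05.

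Genes of the corepressor complex were enriched near peaks of both tissues, and genes of lipid and glucose metabolism near eWAT peaks. Of 30 genes of lipid and glucose metabolism 11 had an eWAT peak (odds ratio 3.50, 1.505 to 7.76, Fisher's exact test, adjusted p = 0.0075). They were led by Acaca (acetyl-CoA carboxylase, rank 334) and included Angptl4, Plin5, Fgf21 and Fads1. In brain 12 had a peak (odds ratio 1.72, Fisher's exact test, adjusted p = 0.309), led by Angptl4 (rank 510) and including Acaca, Insig1, Fasn, Fads1 and Pdk4. The tissues were not called different for this list (6 genes with a peak in eWAT only, 7 in brain only, exact McNemar test, p = 1; against all other genes, Fisher's exact test, adjusted p = 0.355). The eWAT enrichment ended within 1 kb of a start (adjusted p = 0.546, Fisher's exact test) and among peaks scoring above the list median (adjusted p = 0.192). Of the 6 genes of the NCoR/HDAC3 corepressor complex, 4 had an eWAT peak (odds ratio 12.1, 1.73 to 133.7, Fisher's exact test, adjusted p = 0.0157). In brain 5 had one (odds ratio 12.9, 1.45 to 611.6, Fisher's exact test, adjusted p = 0.0215). Within 1 kb these 2 enrichments did not pass (adjusted p = 0.417 and 0.546, Fisher's exact test), nor within 50 kb (0.352 and 0.0811, the latter with 6 of 6 genes near a brain peak against 51.1%), and the brain enrichment did not pass with nearest genes (adjusted p = 0.512). Tbl1x had a shared site (eWAT chromosome X, 74754621 to 74754770, rank 230), Hdac3 ranked 2798 in eWAT, Ncor1 had an eWAT peak only, and Tbl1xr1 and Gps2 brain peaks only. Of 10 heme metabolism genes 2 had an eWAT peak, Urod and Alas1, the rate-limiting enzyme of heme synthesis (chromosome 9, 106137945 to 106138094, intron, rank 126), a count near that of other genes (20% against 14.2%, Fisher's exact test, adjusted p = 0.771). Ppox, Alad, Urod, Hmox1, Uros and Alas1 had a brain peak (6 of 10, Fisher's exact test, adjusted p = 0.0806). The remaining 5 lists passed in neither tissue within 10 kb. With nearest genes hepatocyte genes were less frequent near brain peaks (1 of 20 against 29.6%, odds ratio 0.125, exact test, adjusted p = 0.0358). Of 16 stromal, vascular and immune genes of fat 5 had an eWAT peak, among them Cdh5, Col1a1 and Lyz2, and 4 a brain peak, led by Cd68 with a peak in an intron of Eif4a1. Glia genes had 3 in eWAT and 5 in brain of 18, among the latter Olig1 and Slc1a2, and hepatocyte genes 4 and 2 of 20, with Ass1 in both. Skeletal muscle genes had 1 and 2 of 13. Of 12 housekeeping genes none had an eWAT peak and 5 a brain peak, among them Ywhaz, Actb, Tbp and Gapdh.

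In liver, pairs of opposite-strand borders lay within 10 kb of all 20 hepatocyte genes, against 34.9% of other genes (Fisher's exact test, adjusted p = 5.35e-09). They also lay near 27 of 30 lipid and glucose genes (odds ratio 16.8, 5.16 to 86.5, exact test, adjusted p = 5.02e-09) and 21 of 23 core clock genes (odds ratio 19.6, 4.78 to 172.1, adjusted p = 1.75e-07). Heme genes (9 of 10, exact test, adjusted p = 0.0024) and adipocyte genes (19 of 27, odds ratio 4.42, 1.85 to 11.7, adjusted p = 0.0017) passed as well. The comparison list of housekeeping genes went the same way (8 of 12, odds ratio 3.72, exact test, adjusted p = 0.080). It passed within 1 kb (7 of 12, exact test, adjusted p = 0.0184) and with nearest genes (adjusted p = 0.0408). Pairs were less frequent at neuron genes (2 of 24, exact test, adjusted p = 0.0157) and skeletal muscle genes (0 of 13, Wilson upper bound 22.8%, adjusted p = 0.0186). The hepatocyte call ended within 1 kb (exact test, adjusted p = 0.151). The muscle call ended within 1 kb (exact test, adjusted p = 0.220) and among pairs whose plus border had a signal above the median (adjusted p = 0.203). In both, the muscle count stayed at 0 of 13, against 19.7% and 20.2% of other genes. The neuron call ended within 50 kb, with nearest genes and among pairs above the median (exact test, adjusted p = 0.455, 1 and 0.422).

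**Figure D3:**
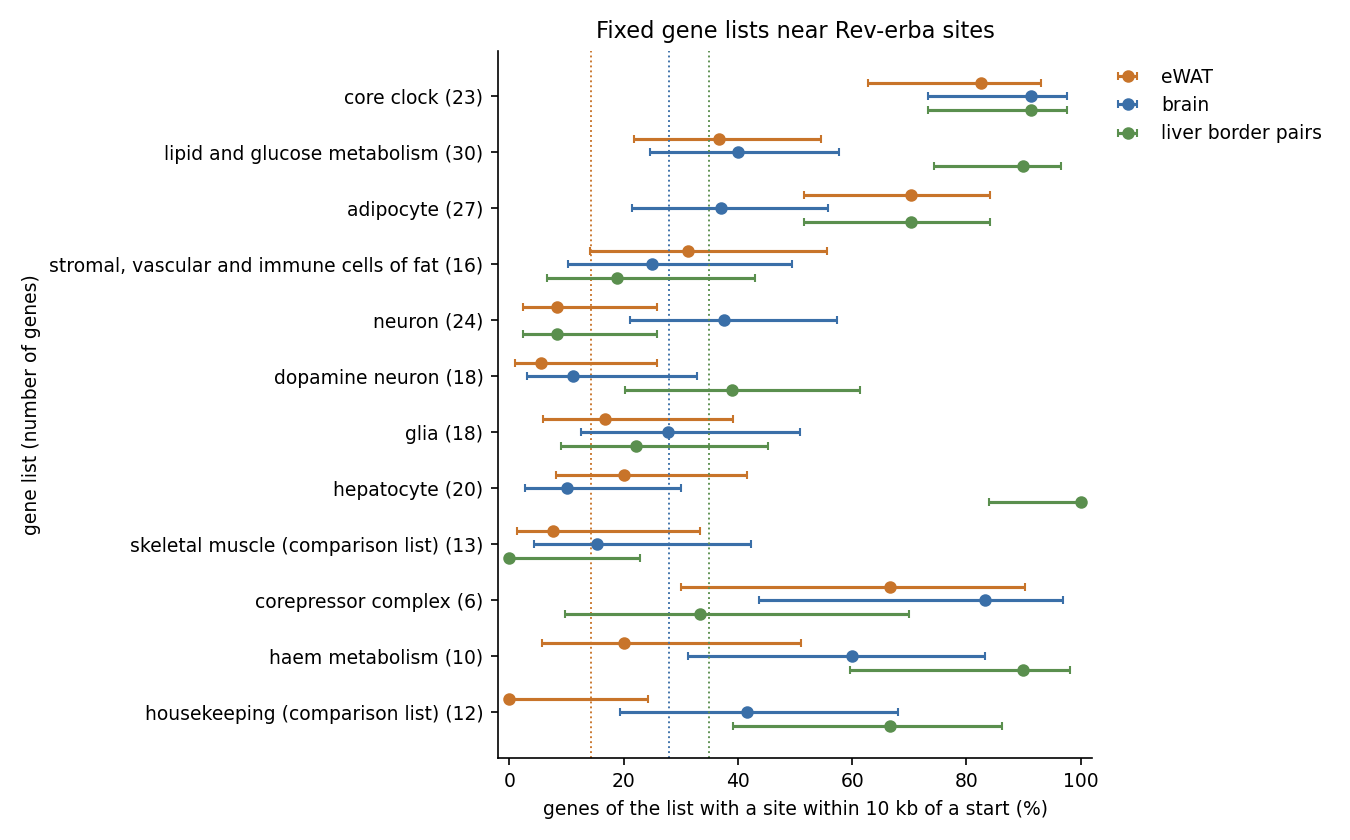
Percentage of the genes of each fixed list (vertical axis, number of genes in parentheses) with an eWAT peak, a brain peak or a liver border pair within 10 kb of a transcription start; bars are 95% Wilson intervals and dotted lines the mean percentage among other protein-coding genes. Core clock genes lie above 80% in all 3 sets (82.6%, 91.3% and 91.3%), adipocyte genes at 70.4% in eWAT and 37.04% in brain, and hepatocyte genes at 100% in liver.

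The tissues also differed in where the sites lay. Brain-only peaks were within 1 kb of a transcription start in 3896 of 9981 cases (39.0%, 38.1 to 40), eWAT-only peaks in 640 of 8310 (7.70%, 7.15 to 8.29) and shared peaks in 150 of 706 (21.2%, 18.4 to 24.4). Brain-only peaks thus exceeded eWAT-only peaks with an odds ratio of 7.67 (7.01 to 8.41), which was 3.53 with a 5 kb window. They exceeded shared peaks with 2.37 (1.97 to 2.87, Fisher's exact test, adjusted p = 1.48e-22), and shared exceeded eWAT-only peaks with 3.23 (2.63 to 3.95, adjusted p = 1.42e-26). Introns outside that window held 44.3% of eWAT-only, 31.3% of brain-only and 42.4% of shared peaks, and intergenic sequence 45.0%, 27.1% and 34.7%. The mean GC content within 50 bp of the centre was 48.5% in eWAT-only, 56.3% in brain-only and 54.9% in shared peaks.

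Since a mutant of the DNA-binding domain is part of the series, the peaks were searched for the elements that Rev-erbα contacts directly, the RORE (AWNTRGGTCA) and the RevDR2 (RGGTCANNRGGTCA). An element lay within 50 bp of the centre of 108 of 706 shared eWAT peaks (15.3%) and 375 of 8310 eWAT-only peaks (4.51%; odds ratio 3.82, 3.01 to 4.83, Fisher's exact test, p = 5.39e-25). In brain one lay in 89 of 706 shared peaks (12.6%) and 226 of 9981 brain-only peaks (2.26%; odds ratio 6.23, 4.75 to 8.10, Fisher's exact test, p = 7.63e-34). The same width 1000 bp away held one in 0.354% and 0.265% of eWAT and 0.779% and 0.321% of brain peaks. Among peaks scoring above the list median the eWAT odds ratio was 2.34. The best peak of 3 of 19 clock genes in eWAT (Npas2, Rora and Cry1) and of 3 of 21 in brain (Npas2, Clock and Rora) had such an element within 50 bp, as had 5.36% of all eWAT and 2.95% of all brain peaks. An E-box CACGTG, the element of CLOCK and BMAL1, was in the best peak of 8 and 7 clock genes.

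Of 15 other motifs, 10 differed between eWAT-only and brain-only peaks. The C/EBP motif was in 7.77% of eWAT-only and 2.81% of brain-only peaks (odds ratio 2.92, 2.53 to 3.38, Fisher's exact test, adjusted p = 3.51e-52). Which factors bind this motif in these tissues was not tested. CTCF (3.35% and 1.40%), AP-1 (3.87% and 2.15%), the core NFI site TTGGCA (14.2% and 9.19%) and the E-box CACGTG (8.18% and 5.30%) were also more frequent in eWAT-only peaks. The GC box was in 0.0842% of eWAT-only and 3.54% of brain-only peaks (odds ratio 0.023; 0.0604 over 1 kb from every start), and ETS (0.698% and 2.82%), RFX (0.0481% and 0.371%) and SOX (3.15% and 4.14%) motifs were more frequent in brain-only peaks. Over 1 kb from every start the ETS difference did not pass (odds ratio 0.852, Fisher's exact test, adjusted p = 0.585). The SOX difference did not pass among peaks scoring above the list median (Fisher's exact test, adjusted p = 0.0508). Its odds ratio there was 0.779, against 0.754 over all peaks. The neural E-box, at 7.03% and 6.20% over all peaks (exact test, adjusted p = 0.0399), was at 7.01% and 7.92% over 1 kb from every start (adjusted p = 0.0761). DR1, the NFI palindrome, HNF6, FOX and MEF2 motifs did not pass.

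**Figure D4:**
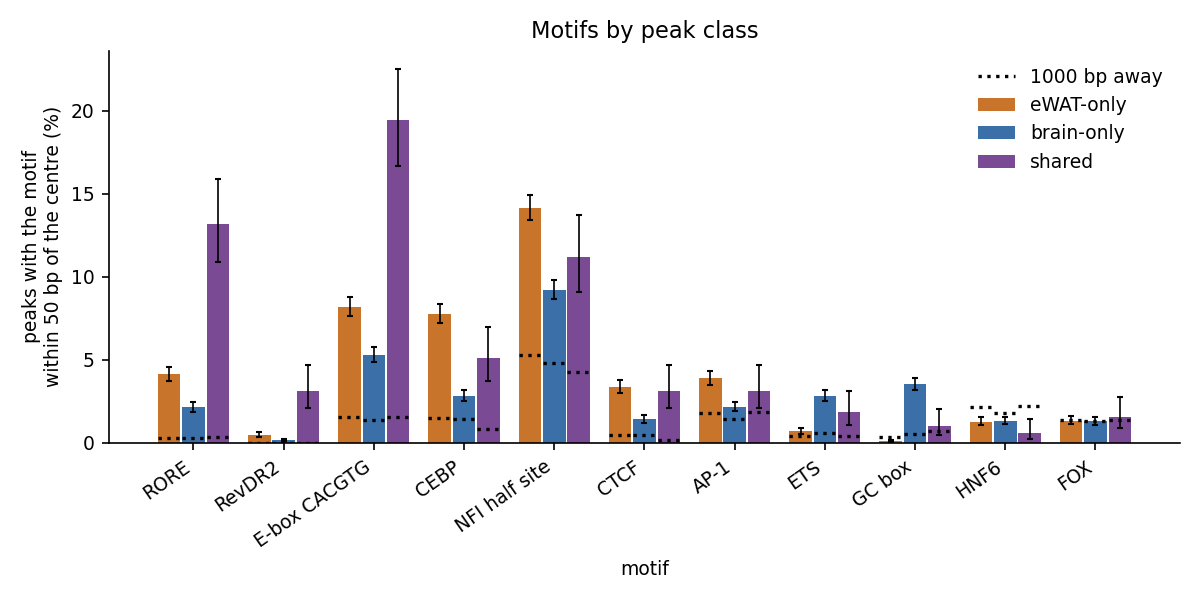
Percentage of eWAT-only, brain-only and shared peaks (bars, with 95% Wilson intervals) that have each motif within 50 bp of the centre, and the percentage in the same width 1000 bp away (dotted lines). The E-box is in 19.4% and the RORE in 13.2% of shared peaks, and HNF6 motifs are in 0.567% of shared peaks against 2.20% 1000 bp away.

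The liver borders were examined for the length of DNA protected at bound sites. The distance from a plus-strand border to the next minus-strand border was most often 25 bp (1557 pairs), and a lesser maximum stood at 29 bp (955 pairs). Of 122296 plus borders, 21.6% had a partner 5 to 60 bp downstream, against 0.838% ± 0.0792 after the minus borders were moved (SD, 100 offsets; permutation test, one-sided, p = 0.0099, the smallest they can give). Read in the opposite orientation, with the minus border first, 9.14% had one (odds ratio 2.74, 2.67 to 2.80). Among borders within 500 bp of an eWAT or brain peak the most frequent distance was 29 bp.

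The 25 bp and 29 bp maxima went with different motifs, in tests chosen after the distances were seen. The search reached 10 bp beyond each border, so a counted motif need not lie between the borders. At 25 bp, 859 of 1557 pairs (55.2%, 52.7 to 57.6) held a motif of HNF6 (Onecut1), a transcription factor of liver, against 1.54% of windows 1000 bp away and 0.917% of pairs in the opposite orientation (Fisher's exact test, adjusted p = 9.08e-288 against the windows). At 29 bp, 385 of 955 pairs (40.3%, 37.3 to 43.5) held a C/EBP motif, against 0.628% and 0.873% (Fisher's exact test, adjusted p = 3.91e-125). At 12 bp, 44 of 517 pairs (8.51%, 6.40 to 11.2) held a FOX motif, against 0.580% and 0.733%, and about as many an HNF6 motif (43 pairs, 8.32%). At 17 bp, 41 of 475 pairs (8.63%) held an HNF6 motif. The HNF6 shares at 12 and 17 bp lay below the 13.4% of all pairs 5 to 60 bp apart. The RORE was in 136 of 26407 pairs (0.515%, 0.436 to 0.609), above the windows (0.148%, Fisher's exact test, adjusted p = 4.00e-13) but not different from the opposite orientation (0.552%, adjusted p = 0.896).

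**Figure D5:**
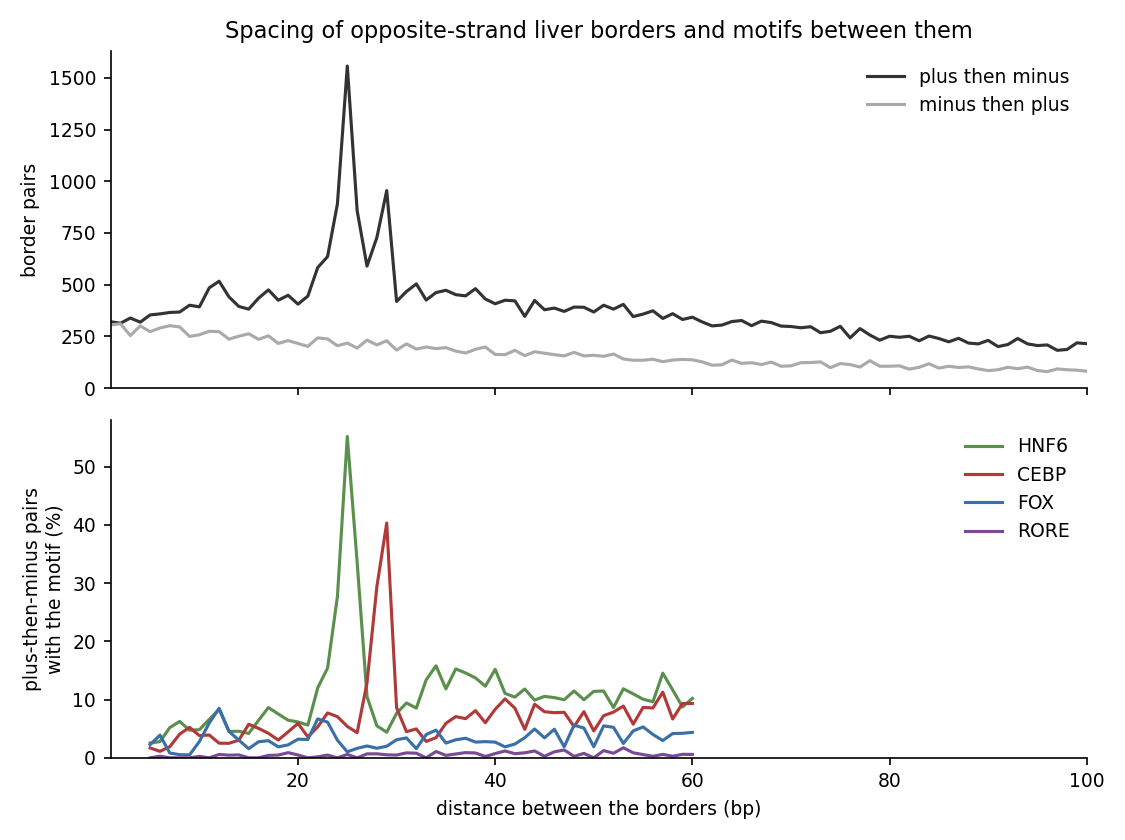
Number of liver border pairs by distance (bp) with the plus border first (dark) or the minus border first (grey), upper panel. The lower panel gives the percentage of plus-first pairs 5 to 60 bp apart with each motif. The motif search reached 10 bp beyond each border. The maximum of 1557 pairs at 25 bp coincides with HNF6 motifs in 55.2% of pairs, and that of 955 pairs at 29 bp with C/EBP motifs in 40.3%.

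Borders were also placed around the RORE itself. Of 940 RORE copies inside eWAT or brain peaks, 118 had a liver border within 20 bp (12.6%), against 561 of 87051 copies elsewhere (0.644%; odds ratio 22.1, 17.8 to 27.4, Fisher's exact test, p = 4.04e-104). Copies of the shuffled consensus TNAACWRGTG gave 5 of 62 (8.06%) and 0.352% (odds ratio 24.8, 7.71 to 62.1), so the contrast was not particular to the RORE. Of 154 RevDR2 copies in peaks 51 had a border (33.1%), against 2.31% elsewhere. The most frequent border positions, counted from 0 at the first base of the RORE, were 8 on the motif strand, with 22 of the 873 borders within 40 bp, and 33 on the other, with 22 of 746. At copies in peaks these positions held 3 of 168 and 4 of 138 borders, where the highest counts, at other positions, were 7 and 6. The positions were not tested against an even spread, so they give no footprint of the RORE.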

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

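The tests of read depth and of chance peaks on the shared sites were chosen after the percentages they bear on were in part known, as was the comparison of adipocyte genes with all other genes; the tests of depth and GC content on the promoter share were chosen before their results were seen.

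Of 15 motifs, 10 differed between eWAT-only and brain-only peaks in a test of the difference itself. The odds ratios (eWAT-only over brain-only) were 2.92 for C/EBP, 2.43 for CTCF, 1.83 for AP-1, 1.63 for the core NFI site, 1.59 for the E-box CACGTG, 1.14 for the neural E-box (reversed over 1 kb from every start), 0.754 for SOX, 0.243 for ETS, 0.129 for RFX and 0.023 for the GC box. Adipocyte genes with a peak in 1 tissue had it in eWAT rather than brain with an odds ratio of 15.4 against all other genes, a difference that did not pass within 50 kb. Outside the chromosomes analysed, the liver list held 32 mitochondrial borders (median signal 6.78, against 0.471 over all borders) and 242 borders on the Y chromosome (median signal 0.825).

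The promoter share of brain-only peaks exceeded that of eWAT-only peaks with an odds ratio of 7.67. If only weak peaks called at a loose threshold gave the excess, the strongest brain peaks would lack it. The top score decile of brain peaks had a promoter share of 48.5% (45.5 to 51.5), against 23.97% in the lowest decile. It lay above the 14.75% of the top eWAT decile and the 7.70% (7.15 to 8.29) of eWAT-only peaks. The excess is therefore not confined to weak brain peaks. A shallow library could also keep mainly strong promoter signals, so this test cannot decide on low depth, which stays open. Within deciles of GC content near the centre the Mantel-Haenszel odds ratio was 3.36 (3.04 to 3.71), below 7.67. The outer deciles were wide (16.8% to 40.6% and 68.3% to 85.2% GC), so GC content still varied within them. In the narrow deciles from 48.5% to 49.5% and from 50.5% to 51.5% GC the odds ratios were 2.12 and 2.94. GC content near the centre is therefore not the whole cause, though it may be a part. GC-rich DNA read more often in the brain library stays open, since the GC content of whole fragments was not measured. Open promoter chromatin that is precipitated without specific binding stays open, since the brain input was not analysed here. A difference between the tissues in where Rev-erbα binds is a hypothesis that was not tested apart from these explanations.

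The small number of sites shared by eWAT and brain (706 in each list) was weighed likewise. A lack of reads in either library would leave the weaker sites of the other list uncalled. Sharing rose with score as this needs, from 3.09% (2.21 to 4.31) in the lowest score decile of brain peaks to 21.7% (19.3 to 24.3) in the highest, and from 2.44% (1.62 to 3.67) to 32.9% (29.9 to 36.1) in eWAT. Too few reads therefore fit as a cause and stay open, although other causes could give the same rise. If the score steps are read counts, the median brain peak held 7 and the median eWAT peak 14. Read totals are not given, so these steps do not settle the depth of either list. Chance peaks at random places would have a liver border no more often than moved peaks. In the lowest score decile of brain-only peaks 17.8% (15.6 to 20.3) had one. Peaks moved by 10 to 100 kb gave 2.37% ± 0.476 (permutation test, one-sided, p = 0.001, the smallest possible). These peaks therefore do not all lie at random places. In the lowest decile of all brain peaks 23.97% lay within 1 kb of a start, a placement that moving does not keep. Background peaks at promoters could also meet liver borders more often, so the test cannot separate them from bound sites. An unknown part of these peaks may be chance or background. Differences in enrichment efficiency between the precipitations stay open, as does binding that differs between the tissues, which no replicate of brain could test.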

How the results depend on the processing

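No paired analysis was possible because the files hold 1 list per group and no value per replicate; leaving out a replicate and a replicate block were therefore not run. Of the 107 recomputed values of results that answer a comparison, 98 kept their direction and side of the threshold (counts within 1.5 times) and 9 moved. Among peaks scoring above the list median, the number of shared peaks was 435 in each list, from fewer peaks entering. The most frequent distance between opposite-strand borders was 29 bp within 500 bp of a peak. The number of gene lists differing between eWAT and brain was 0 and became 1 against all other genes, 1 within 50 kb and 2 with nearest genes. Lists enriched in eWAT fell from 4 to 2 within 1 kb. In brain they fell from 2 to 1 within 1 kb and to 1 within 50 kb. A count of lists called the same can still lose or change lists. With nearest genes, neuron genes passed in brain (Fisher's exact test, adjusted p = 0.0358) and corepressor genes did not (adjusted p = 0.512). Of 158 values for single motifs and lists, 130 stayed the same, 19 lost and 6 gained significance, and 3 turned direction on the log2 odds scale (0.5 added to each cell), none of them passing: the neural E-box at -0.19 over 1 kb from every start, neuron genes near brain peaks at -0.0303 within 1 kb, and dopamine neuron genes near eWAT peaks at 0.0593 among peaks scoring above the median. Without the added 0.5 the dopamine neuron genes kept their direction, with an odds ratio of 0.715 among these higher-scoring eWAT peaks. Apart from the counts whose construction shows it, the cause was not tested. The lengths of the lists rest on the authors' thresholds and unknown depth, which limit every percentage of shared sites. The opposite orientation, the distance to starts, the comparison with all other genes, the motifs at border pairs and the matched brain list were chosen after seeing the data.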

Other observations

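The test of the HNF6 sites against the eWAT and brain lists, and all values for E-boxes by sharing and for C/EBP pairs, were chosen after related results were seen; the test for repeated sequence was chosen before its result was seen.

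Sites shared by eWAT and brain carried the clock E-box more often than sites of 1 tissue. CACGTG lay within 50 bp of the centre of 137 of 706 shared eWAT peaks (19.4%) and 680 of 8310 eWAT-only peaks (8.18%; odds ratio 2.70, 2.19 to 3.32, Fisher's exact test, p = 5.10e-19), and of 129 of 706 shared brain peaks (18.3%) and 529 of 9981 brain-only peaks (5.30%; odds ratio 4.00, 3.21 to 4.94, p = 3.72e-31). Over 1 kb from every start the odds ratios were 1.99 and 4.69, and in the highest score quartile 2.15 and 2.96. Shared peaks scored higher, and the E-box share rose with score. From the lowest to the highest decile it went from 5.1% to 25.6% in eWAT and from 3.28% to 15.15% in brain. The ratios over all peaks therefore also carry differences in score. Against sequence 1000 bp away, the odds ratio in shared peaks was 15.2 (9.52 to 25.3) for the E-box and 42.7 (17.5 to 135) for the longer RORE, and these were not tested against each other. The overlap of these elements in single peaks was not counted.

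In liver, HNF6 motifs were most frequent in border pairs 25 bp apart (859 pairs, 55.2%), against 27.7% at 24 bp, 33.6% at 26 bp and 13.4% of all pairs 5 to 60 bp apart. The 25 bp pairs were not tested against other pairs with the motif. Identical copies of a repeated sequence are argued against, since 100% of the 859 pairs had a sequence between the borders found in no other pair (lower bound 99.6%). Repeat copies that differ by a base would also pass this test, so repeats that are not identical stay open. A candidate explanation is a site held by a liver factor. Of the 852 such pairs without a RORE, 0.822% lay within 100 bp of an eWAT or brain peak, against 27.1% of the 118 pairs 5 to 60 bp apart with a RORE and no HNF6 motif (odds ratio 0.0223, 0.0081 to 0.0538, Fisher's exact test, p = 6.88e-25). Of C/EBP pairs 29 bp apart 19.5% lay near a peak, and of all pairs 10.2%. The spacings of these sets differ, and an effect of spacing was not separated. The contrast with RORE pairs cannot decide on a liver factor, since the peaks themselves differ in these motifs. Shared peaks held the RORE in 13.2%, against 0.354% in sequence 1000 bp away, and HNF6 motifs in 0.567%, against 2.2%. Peaks of eWAT only and of brain only went the same way. The percentages therefore show only that these HNF6 pairs rarely lay near a listed peak. A sequence preference of the exonucleases and binding of HNF6 by the antibody remain open, since no ChIP-exo library without Rev-erbα was analysed here, and whether Rev-erbα is recruited there by HNF6 was not tested.

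Genes near a site of all 3 sets numbered 952 of 22350, from 3176 near an eWAT peak, 6236 near a brain peak and 7819 near a liver border pair. No chance level was computed for this count, and what holds the liver pairs is open as stated above.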
